A study of Homo sapiens with 10 samples.

How the data were processed

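MiRNA levels were measured on the NanoString nCounter, which counts barcoded probes without amplification, in MCF7 and MCF10A cells and in the extracellular vesicles (EVs) that these cells released. Per the labels' protocols, cells were grown with serum to near confluence and then kept serum-free for 72 hours, EVs were taken from that medium, and RNA was extracted with TRIzol and purified by ethanol precipitation. The labels also give assumed recoveries, of 75% for TRIzol extraction of cell RNA and 10% for that of EV RNA, 100% and 19% for the ethanol step, and 15% for EV isolation. Whether these were used to scale the values is not stated.

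The deposited values are log2 normalised values for 141 of the 654 miRNAs that were assayed per the labels. The authors' rule for choosing the 141, their background treatment and their scaling are stated in no label or header used here. In each sample, 2 to the power of the value was a whole multiple of a single step, with 100% of the values whole within 0.01 and a largest deviation of 1.08e-05. The deposited log2 values therefore correspond to whole-number counts, 1 or above, times 1 factor per sample. The per-sample medians of the deposited log2 values lay between 6.97 and 7.12. The step recovers counts for the listed miRNAs alone, so their sum is not the whole depth of a lane. The main test had been laid out for normalised values or for raw counts, and since the unit was log2, limma was used.

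The number of miRNAs at the lowest count separated 6 samples with 9 to 21 such miRNAs from 4 samples with 0 to 2. These sets are called the first and the second run below. The grouping was drawn from the values, with 5 such miRNAs or more marking the first run, and the labels name no run. The first run held both MCF7 EV samples, the MCF10A EV sample, MCF7 cells 1 and 2 and MCF10A cells 1, and the second held MCF7 cells 3 and 4 and MCF10A cells 2 and 3. A count of 2 or less was taken as the lowest, and 118 miRNAs were never there while 23 were there in 1 or more samples.

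The groups, the tests, the miRNA lists, the rule for the miRNAs named in the text and most alternatives were chosen before the data were examined. The run, the filters on the lowest count and on a deposited log2 value of 8, the values without a pseudocount and limma-voom on recovered counts were added after it. Values were taken as deposited, log2 of the value plus a pseudocount of 1 was computed, and all 141 miRNAs were kept. A linear model with 4 groups was fitted to all 10 samples with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), so that every comparison shared 1 estimate of spread with 7.79 degrees of freedom. The 1 MCF10A EV sample was assumed to vary like the other groups. The p-values were adjusted by Benjamini-Hochberg over the 141 miRNAs within each comparison, with a threshold of 0.05. Every adjusted p below comes from limma or, for lists, from limma's camera. The p-values measure the spread between these samples, which may be technical, since the labels do not say whether the replicates were separate cultures.

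The 25 miRNA lists covered families, genomic clusters, luminal and basal breast epithelial markers, EV-associated miRNAs, miRNAs described as promoting breast cancer, and markers of other cells or of serum. The 14 lists with 3 or more listed members were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data. None of the names on the haematopoietic, the liver and serum, and the pluripotent and placental lists was among the 141. Named in the text are up to 10 miRNAs per direction with the largest differences among those past the threshold whose groups did not overlap, the 5 largest where fewer than 5 passed, the 10 most abundant in MCF7 EVs, all members of the miR-200, miR-221/222, miR-183, luminal and basal lists, and up to 4 abundant members of other lists. Other names were chosen after their values were seen. Names were matched to miRNA genes of the RefSeq table for GRCh38.p14, in which 136 of the 141 had an entry and 5 had none (miR-720, miR-1274a, miR-1274b, miR-1308 and miR-1979).

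The fits were tested on simulated data for the same 141 miRNAs and groups, with 40 miRNAs changed. At a log2 change of 2, the share of changed miRNAs recovered was 57.5% for MCF7 EVs against MCF10A EVs, 85% for MCF7 cells against MCF10A cells, and 60% for MCF7 EVs against MCF7 cells as well as for MCF10A EVs against MCF10A cells. At a log2 change of 1 it was 0% for the EV comparisons and 32.5% for the cells. False calls numbered between 0 and 4. The simulated values were independent normal draws with the same spread for a miRNA in all groups, without a run effect or lowest counts. They assume that the MCF10A EV sample varies like the others, so these rates do not give the error rates of the real data. The alternatives covered scaling, pseudocount, filters, the variance model, the samples in the fit, the replicate number or the run as a block, each run alone, limma-voom and the omission of each sample in turn. Shares of a single sample carry Wilson intervals at the 95% level, which cover counting error only.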

Results

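MiRNAs were measured in 10 samples from a pair of human breast epithelial lines. MCF7 is an oestrogen receptor positive, luminal breast cancer line, and MCF10A is a non-tumorigenic breast epithelial line with basal features. There were 4 samples of MCF7 cells, 3 of MCF10A cells, 2 of MCF7 EVs and 1 of MCF10A EVs. Levels of 141 miRNAs were listed for every sample. The recovered counts over these 141 summed to 115152, 179181, 69000 and 161710 in MCF7 cells 1 to 4, and to 81247, 55852 and 111898 in MCF10A cells 1 to 3. They summed to 145214 and 183481 in MCF7 EVs 1 and 2 and to 50458 in the MCF10A EV sample. The 10 highest miRNAs held between 48.4% and 85.2% of a sample's signal. Replicates differed by far more than counting error, with chi-square per degree of freedom between 65.8 and 175 for pairs of replicates. Differences below are on the log2 scale with the standard error (SE) of the fit. Members of a family with near-identical sequences, such as the let-7 miRNAs, may share signal between probes, so they are not independent readings.

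The first question of the series was which miRNAs were abundant in MCF7 EVs. MiR-720 alone held 47.1% ± 5.73 (SD, n = 2) of the MCF7 EV signal. It was followed by miR-1274b with 6.60% ± 0.80, miR-1274a with 6.08% ± 0.68, miR-1260 with 5.16% ± 1.49, miR-100 with 4.59% ± 0.25 and miR-630 with 2.47% ± 0.57 (SD, n = 2 each). MiR-720, miR-1274a and miR-1274b have since been withdrawn from miRBase as fragments of tRNA, and they have no miRNA gene in the GRCh38.p14 table. MiR-125b (2.22%), miR-21 (2.06%), let-7a (1.75%) and miR-92a (1.69%) completed the 10 highest by mean value. In the MCF10A EV sample, miR-630 came first with 25.1% (Wilson 95% interval 24.7 to 25.5) and miR-720 next with 15.8% (15.5 to 16.1). The 20 most abundant miRNAs held 88.0% ± 4.51 of the MCF7 EV signal (SD, n = 2). Of these 20, 14 were also among the 20 highest in MCF7 cells and 14 among the 20 highest in the MCF10A EV sample.

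MCF7 EVs were compared with MCF10A EVs to find the largest fold differences between cancer-derived and non-tumorigenic EVs. MiR-21, an oncogenic miRNA that represses PDCD4 and PTEN, was 12.1-fold higher in MCF7 EVs (log2 3.60, SE 0.71, n = 2 against 1). MiR-200b, which represses the mesenchymal regulators ZEB1 and ZEB2, was 8.40-fold higher (log2 3.07, SE 0.47), and miR-23b was 3.98-fold higher (log2 1.99, SE 0.32). MiR-205, a marker of basal breast epithelium, was 62.0-fold lower (log2 -5.95, SE 0.73). These were the 4 miRNAs past the threshold, 3 higher and 1 lower, with adjusted p of 0.0365 for miR-21, 0.0126 for miR-200b and miR-23b, and 0.00638 for miR-205. With every sample scaled to the same total, 0 were higher and 5 lower by limma (27 at an unadjusted p under 0.05; 8 past the threshold by limma-voom on recovered counts with the deposited scaling), and of the 4 only miR-205 kept its call. Scaled to the geometric mean of the 100 highest or by median ratio all 4 kept their calls, and with quantile normalization miR-23b and miR-205 did. With only the EV groups fitted, all 4 lost their calls. Of the 20 most abundant miRNAs, 15 were higher in MCF7 EVs than in the MCF10A EV sample. In fold order miR-21 came first and was the 1 of the 20 past the threshold. It was followed by miR-1979 (10.8-fold, adjusted p = 0.0524) and miR-1274b (6.57-fold, adjusted p = 0.198). MiR-720 (5.80-fold, adjusted p = 0.322), miR-125b (5.54-fold, adjusted p = 0.125) and miR-100 (4.28-fold, adjusted p = 0.114) did not pass either, nor did miR-1260 (6.02-fold), miR-1274a (3.63-fold), let-7a (2.39-fold) or, among the less abundant, let-7f (11.2-fold, adjusted p = 0.0524). The next in size below the MCF10A EV sample, after miR-205, did not pass. They were miR-1246 (log2 -4.91, SE 3.99, at the lowest count in MCF7 EVs 1), miR-1290 (7.82-fold, log2 -2.97), miR-30e (7.72-fold, -2.95) and miR-19b (6.43-fold, -2.68, adjusted p = 0.0524). MiR-630 (-2.40, SE 3.03) and miR-92a (-0.20) did not pass.

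Among the lists, 1 of 5 members of the miR-200 family rose, miR-200b, and 3 rose when adjusted over the list alone. MiR-200a (log2 1.98), miR-200c (1.40) and miR-141 (1.35) did not pass over all miRNAs, nor did miR-429 (-0.13), and camera gave an adjusted p = 0.106. Of the 11 luminal markers 1 rose, miR-200b, and 1 adjusted over the list alone, with camera adjusted p = 0.0509, or adjusted p = 0.334 with an estimated correlation. MiR-375 (1.41), miR-342-3p (1.64), miR-96 (1.74), miR-183 (0.49) and miR-29c (0.16) did not pass. MiR-26a (3.77, SE 3.96) did not pass either and was at the lowest count in the MCF10A EV sample and in MCF7 EVs 1, so its difference rests on MCF7 EVs 2. Of the 7 basal markers 1 fell, miR-205, while 2 rose and 1 fell adjusted over the list alone, the 2 being miR-100 and miR-125b. MiR-221 (-1.15), miR-222 (1.16), miR-31 (-0.95) and miR-22 (-0.20) did not pass. Of the 6 breast cancer oncomiRs miR-21 rose, and it was also the 1 adjusted over the list alone. In the miR-23/27/24 clusters miR-23b was the 1 of 4 that rose, also adjusted over the list alone. The medians of these last lists turned from 0.94 to -0.01 and from 0.10 to -0.86 with every sample scaled to the same total, which shifted the median over all miRNAs by -0.95. The single MCF10A EV sample was assumed to vary like the other groups, and no call remained without MCF7 EVs 2, where limma left 0 miRNAs past the threshold and 15 at an unadjusted p under 0.05. All 3 EV samples were in the first run, so the EV differences were the same with the run as a block, where 10 miRNAs passed (5 higher, 5 lower), and within the first run, where 14 passed (8 higher, 6 lower) with all spread taken from the MCF7 pairs. These counts change the spread alone and lend the 4 calls no support of their own. MiR-21 kept its call in 16 of 27 alternatives and lost it without any 1 of 7 samples, all except MCF7 cells 3 and 4 and the MCF10A EV sample, which could not be left out. The 16 include filter settings that removed 0 miRNAs and so could not change the call.

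**Figure D1:**
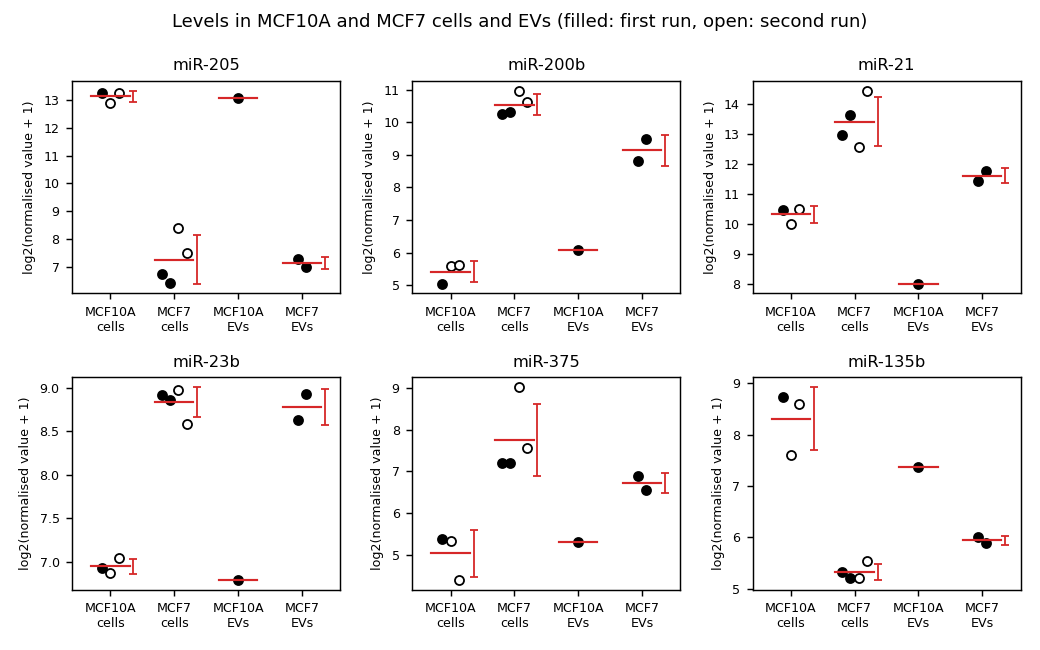
Levels of miR-205, miR-200b, miR-21, miR-23b, miR-375 and miR-135b, as log2 of the normalised value plus 1, in each sample of the 4 groups. Filled points are samples of the first run and open points of the second, red lines are group means and red bars 1 SD; miR-205 lay between 12.91 and 13.25 in MCF10A cells, at 13.08 in the MCF10A EV sample, and between 6.41 and 8.38 in MCF7 cells.

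MCF7 cells were compared with MCF10A cells to see which EV differences were also present in the cells. MiR-200b was 34.8-fold higher in MCF7 cells (log2 5.12, SE 0.29, n = 4 against 3), miR-21 8.53-fold higher (3.09, SE 0.44) and miR-375, an miRNA enriched in luminal breast tumours, 6.53-fold higher (2.71, SE 0.50). MiR-205 was 59.1-fold lower (-5.88, SE 0.46) and miR-135b 7.93-fold lower (-2.99, SE 0.30). Some miRNAs of the MYC-driven miR-17-92 cluster and its paralogues, 5 of 9 listed, were also lower, with miR-20a+miR-20b at -2.66 (SE 0.65), miR-19b at -2.62 (SE 0.38), miR-92a at -2.23 (SE 0.53), miR-18a at -2.20 (SE 0.28) and miR-106a+miR-17 at -1.95 (SE 0.24), while miR-19a (-1.95, SE 0.72) did not pass. In all, 44 miRNAs passed the threshold, 24 higher and 20 lower, with adjusted p of 2.1e-05 for miR-200b, 0.00227 for miR-21, 0.0067 for miR-375, 0.000111 for miR-205 and 0.000495 for miR-135b. Other rises were those of miR-200a (2.46), miR-342-3p (2.04), miR-23b (1.89), miR-429 (1.84), miR-99a (1.69), miR-191 (1.43) and miR-151-5p (1.33). Further falls were those of miR-548g (-2.54), miR-1274a (-2.26) and miR-31 (-1.87).

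Of the 11 luminal markers 7 rose in MCF7 cells, and 7 adjusted over the list alone (camera adjusted p = 0.000254, or adjusted p = 0.105 with an estimated correlation). These were miR-200b, miR-375, miR-200a, miR-141 (2.15), miR-342-3p, miR-429 and miR-183 (0.99). MiR-96 (0.63), miR-29c (0.62), miR-200c (0.14) and miR-26a (4.94, SE 2.47, at the lowest count in MCF10A cells 1) did not pass. In the miR-200 family 4 of 5 rose, and 4 adjusted over the list alone (camera adjusted p = 0.00759, or adjusted p = 0.105 with an estimated correlation). Of the 7 basal markers 3 fell, miR-205, miR-31 and miR-221 (-1.68), and 4 fell adjusted over the list alone (camera adjusted p = 0.176). MiR-22 (-0.90), miR-222 (-0.48), miR-100 (0.46) and miR-125b (0.32) did not pass over all miRNAs. In the miR-17-92 and paralogous clusters 5 of 9 fell and 1 rose, miR-25 (0.91), a member of the miR-106b cluster, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.176, so the list as a whole did not pass). Of the 6 breast cancer oncomiRs miR-21, miR-183 and miR-210 (1.32) rose and miR-221 fell, and 3 rose and 1 fell adjusted over the list alone. The medians of the luminal, miR-200, basal and miR-17-92 lists kept their signs under all 4 other scalings, of which scaling to the same total shifted the median over all miRNAs by 0.30 and gave 25 higher and 12 lower.

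The cell comparison had samples of both runs, though the first held 1 sample of MCF10A cells, so that its spread came from the MCF7 pairs alone. Within the first run 26 miRNAs passed (10 higher, 16 lower), within the second 22 (11 higher, 11 lower), and with the run as a block 58 (29 higher, 29 lower), all 44 among them. All 44 had the same sign in both runs, but they were called from these same samples, so this is no independent support. MiR-200b differed by 5.24 and 5.19 in the first and second run, miR-21 by 2.84 and 3.27 and miR-375 by 1.81 and 3.43. MiR-205 differed by -6.67 and -5.15 there, and miR-135b by -3.47 and -2.72. Others were smaller in the first run and lost their calls there, with miR-191 at 0.48 and 2.12, miR-151-5p at 0.65 and 1.73 and miR-99a at 1.14 and 2.34. MiR-200a, miR-20a+miR-20b, miR-1274a, miR-92a and miR-31 lost theirs within the second run, and miR-141, miR-183 and miR-221 within each run. The luminal median was 1.57 in the first run and 2.15 in the second, and that of the miR-17-92 list -2.48 and -1.78. The count fell to 18 without MCF10A cells 3, to 26 without MCF7 cells 4 and to 28 without either MCF7 EV sample, whose spread entered the shared estimate. Without MCF10A cells 3 the calls of miR-141, miR-342-3p, miR-99a, miR-191, miR-151-5p, miR-1274a, miR-31, miR-20a+miR-20b and miR-92a ended, and without MCF10A cells 1 or 2 respectively those of miR-20a+miR-20b or miR-92a ended too. Of these, miR-141, miR-342-3p, miR-99a, miR-191, miR-1274a and miR-31 also lost their calls without any 1 of 3 or more other samples. MiR-375 and miR-99a lost their calls with limma-voom. MiR-141 was the 1 miRNA named here past the threshold whose groups overlapped.

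The differences between the lines were set side by side in EVs and in cells, which share no sample. Across the 141 miRNAs, which are not independent replicates, the EV difference rose with the cell difference (Pearson r = 0.65, Spearman rho = 0.64, slope 0.61). With the cells of the first run alone r was 0.72, and with those of the second run alone it was 0.62, over the 118 miRNAs never at the lowest count. Of the 44 miRNAs that passed in cells, 41 had the same sign in EVs, as had 112 of all 141. All 3 miRNAs higher in MCF7 EVs were among the 24 higher in MCF7 cells, where independent lists would share 0.511, and miR-205 was the 1 that fell in both, where they would share 0.142. The lists are not independent, since both comparisons used the same estimated spread for each miRNA. An miRNA of low spread passes more easily in both, so these expected numbers are too low.

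**Figure D2:**
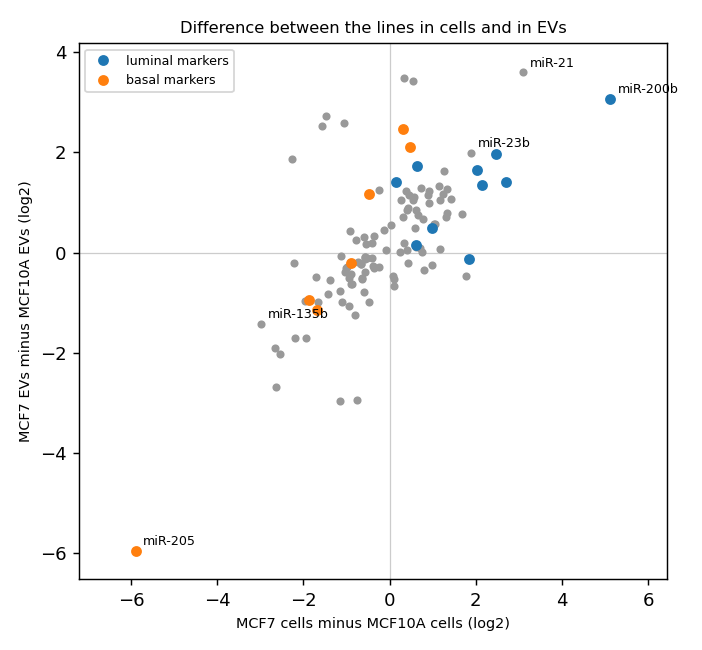
Difference between MCF7 and MCF10A in cells (horizontal, log2) and in EVs (vertical, log2) for the 118 miRNAs never at the lowest count. Each point is 1 miRNA, with luminal markers in blue and basal markers in orange; miR-205 lies at -5.88 and -5.95, miR-200b at 5.12 and 3.07, and the correlation across these miRNAs is 0.67.

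MCF7 EVs were compared with MCF7 cells, to see which miRNAs were over- or under-represented in EVs. Nothing shows that the replicate numbers pair EV samples with cell samples. The tRNA fragments miR-1274a (25.1-fold, log2 4.65, SE 0.75, n = 2 against 4), miR-1274b (18.8-fold, 4.24, SE 0.83) and miR-720 (16.3-fold, 4.03, SE 0.94) were higher in EVs, as were miR-1290 (10.1-fold, 3.33, SE 0.64) and miR-1979 (9.32-fold, 3.22, SE 0.55). MiR-630 was higher by 9.15 (SE 2.14), a size that rests on its lowest counts in MCF7 cells 1 and 2. Its level was 5.31 and 4.44 in MCF7 cells 3 and 4 and 11.95 and 11.87 in the EV samples. Of the let-7 miRNAs, which repress RAS and HMGA2, 6 of 9 were lower in EVs, with let-7f at -3.18 (SE 0.55), let-7i at -2.07 (SE 0.39) and let-7a at -1.55 (SE 0.29). MiR-26b and miR-32 were at the lowest count in both EV samples and above it in all 4 cell samples. No fold is given for them, since lower depth did not explain such counts in MCF10A cells 1 of the same run, and both lost their calls with limma-voom. In all, 38 miRNAs passed the threshold, 11 higher and 27 lower, with adjusted p of 0.0092 for miR-1274a and let-7f, 0.0105 for miR-1274b, 0.0192 for miR-720 and miR-630, and 0.00994 for miR-1290, let-7i and let-7a. Other rises were those of miR-1260 (2.57), miR-423-5p (1.56), miR-222 (1.35) and miR-421 (1.10). MiR-454 (-5.02), miR-148b (-4.28) and miR-101 (-3.85) fell too, with 1 count each in MCF7 EVs 1 and 28, 80 and 39 counts in MCF7 EVs 2, so their sizes rest on a lowest count, and all 3 lost their calls with limma-voom. Other falls were those of miR-15a (-2.79), miR-141 (-2.57), miR-96 (-2.53) and miR-21 (-1.81).

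Of the 9 let-7 members 6 fell, and 6 adjusted over the list alone (camera adjusted p = 0.0015, or adjusted p = 0.159 with an estimated correlation). The let-7 median was -1.71, and -1.51 within the first run. All 3 listed members of the miR-15/16 family, which represses BCL2, fell, miR-15a, miR-16 (-1.70) and miR-15b (-1.62), and 3 adjusted over the list alone (camera adjusted p = 0.0293, or adjusted p = 0.142 with an estimated correlation). In the miR-200 family 4 of 5 fell, miR-141, miR-429 (-1.76), miR-200b (-1.40) and miR-200c (-1.20), and 4 adjusted over the list alone (camera adjusted p = 0.0305, or adjusted p = 0.142 with an estimated correlation), while miR-200a (-0.66) did not pass. Luminal markers fell in 6 of 11, and 6 adjusted over the list alone (camera adjusted p = 0.00339, or adjusted p = 0.142 with an estimated correlation). These were the same 4 with miR-96 and miR-183 (-0.95), and miR-375 (-1.02), miR-342-3p (-0.33), miR-29c (-1.40) and miR-26a (-6.72, SE 2.80, at the lowest count in MCF7 EVs 1) did not pass. Of the 5 EV-associated miRNAs 4 rose, miR-630, miR-720, miR-1290 and miR-1260, and 4 adjusted over the list alone (camera adjusted p = 0.00339, or adjusted p = 0.142 with an estimated correlation), while miR-1246 (1.75) did not pass. Of the 7 basal markers 1 rose, miR-222, and 1 adjusted over the list alone, with camera adjusted p = 0.0305, or adjusted p = 0.471 with an estimated correlation. Their median of 0.90 turned to -0.02 with every sample scaled to the same total, and the list no longer passed there, with the run as a block, within the first run or without MCF7 EVs 1. MiR-100 (1.21), miR-125b (0.90), miR-221 (0.93), miR-31 (0.61), miR-22 (0.42) and miR-205 (-0.12) did not pass.

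Within the first run 45 miRNAs passed (15 higher, 30 lower), 32 of the 38 among them, and with the run as a block 47 passed (13 higher, 34 lower), 37 of the 38 among them. The second run held no EV sample. All 38 had the same sign in the first run, where miR-1274a differed by 4.35, miR-720 by 3.25 and let-7f by -3.32. The 38 were called from a fit that included those samples, so this is no independent support. Without MCF7 EVs 1 limma left 0 miRNAs past the threshold and 33 at an unadjusted p under 0.05, without MCF7 EVs 2 it left 19 past the threshold, and without MCF7 cells 4 it left 25. The calls of miR-630, miR-720, miR-1290, miR-26b, miR-32, miR-21, miR-141, miR-183, miR-200c, miR-429, miR-222, miR-423-5p and miR-421 ended without MCF7 EVs 2, and those of miR-32, miR-148b, miR-454, miR-141, miR-423-5p, miR-421 and miR-222 without MCF7 cells 4. Without MCF7 cells 1 or MCF7 cells 2 the calls of miR-32, miR-148b, miR-454, miR-141, miR-423-5p and miR-421 ended. MiR-21 also lost its call without MCF7 cells 2, and without MCF10A cells 3 so did miR-21, miR-141, miR-148b, miR-423-5p and miR-421. The call of miR-148b also ended without MCF7 cells 3, and that of miR-421 without MCF10A cells 1 or 2. Scaling to the same total shifted the median over all miRNAs by -0.90 and gave 7 higher and 49 lower, and median ratio scaling shifted it by 0.27 and gave 16 higher and 20 lower, so the balance of rises and falls is relative to the scaling, though no named miRNA past the threshold changed its sign. With the same total miR-423-5p (0.65), miR-222 (0.43) and miR-421 (0.19) lost their calls, with median ratio scaling miR-21, miR-141 and miR-183 did, and with quantile normalization miR-720, miR-1290, miR-421, miR-32, miR-141, miR-200b, miR-429 and miR-183 did.

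**Figure D3:**
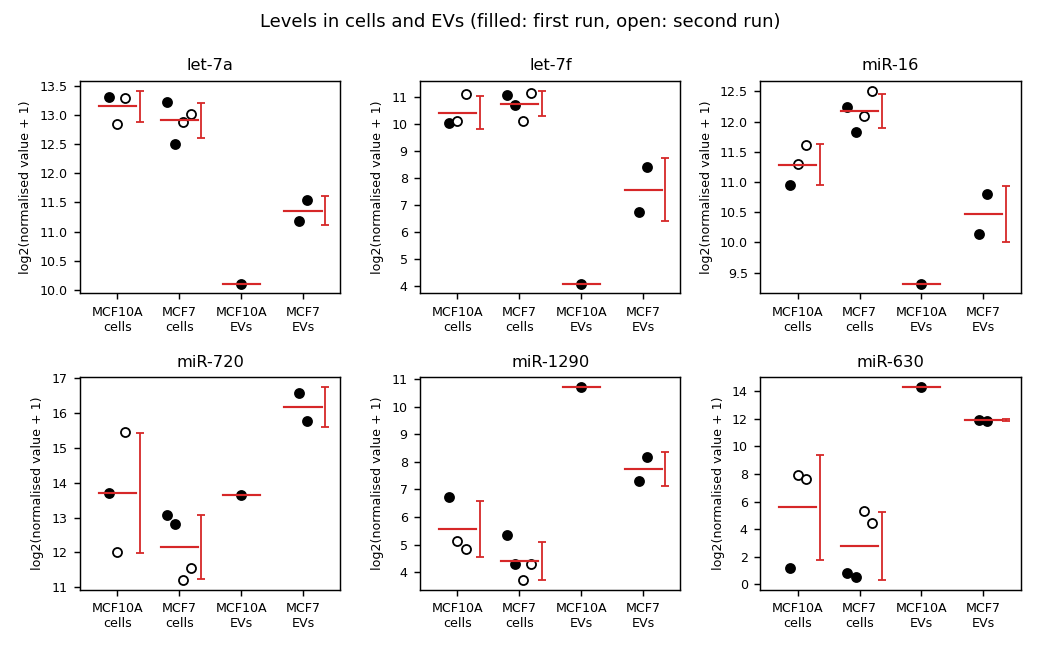
Levels of let-7a, let-7f, miR-16, miR-720, miR-1290 and miR-630, as log2 of the normalised value plus 1, in each sample of the 4 groups. Filled points are samples of the first run and open points of the second, red lines are group means and red bars 1 SD; let-7f lay between 10.11 and 11.15 in MCF7 cells, between 6.76 and 8.40 in MCF7 EVs and at 4.10 in the MCF10A EV sample.

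MCF10A EVs were compared with MCF10A cells in the same way, with n = 1 against 3. MiR-1290 was 35.3-fold higher in the EV sample (log2 5.14, SE 0.85). Let-7f was 80.1-fold lower (-6.32, SE 0.73), miR-96 12.3-fold lower (-3.63, SE 0.60), let-7a 8.27-fold lower (-3.05, SE 0.38) and let-7d 6.79-fold lower (-2.76, SE 0.40). The miRNAs past the threshold numbered 12, with 1 higher and 11 lower, and the adjusted p was 0.00671 for miR-1290 and miR-96, 0.00363 for let-7f and let-7a, and 0.00571 for let-7d. Let-7f, with 10 recovered counts in the EV sample, and miR-96, with 25, lost their calls with limma-voom, where 12 passed. With quantile normalization and with only these groups fitted, limma left 0 past the threshold (28 and 20 at an unadjusted p under 0.05). The other falls among those named were miR-200c (-2.47), miR-15b (-2.46), miR-103 (-2.18), let-7g (-2.04), miR-16 (-1.97) and miR-29a (-1.84). MiR-630 (8.73, SE 2.86, adjusted p = 0.109) did not pass over the 10 samples. It had 14.32 in the EV sample, 7.96 and 7.62 in MCF10A cells 2 and 3 and the lowest count in MCF10A cells 1, on which the fitted size rests. MiR-1246 (4.54, SE 3.76, adjusted p = 0.527) did not pass, with 9.89 in the EV sample, 7.96 and 6.91 in MCF10A cells 2 and 3 and the lowest count in MCF10A cells 1. MiR-1283 (2.38, SE 2.56) and miR-30e (1.74, SE 0.95), the next in size above the cells, did not pass.

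Of the 9 let-7 members 4 fell, and 7 adjusted over the list alone (camera adjusted p = 0.00012, or adjusted p = 0.170 with an estimated correlation), with a median of -1.97 and of -2.39 within the first run. In the miR-15/16 family 2 of 3 fell, and 3 adjusted over the list alone (camera adjusted p = 0.041, or adjusted p = 0.170 with an estimated correlation). That list did not pass with the run as a block, within the first run, or without MCF10A cells 1, MCF10A cells 2 or either MCF7 EV sample. Of the 5 EV-associated miRNAs 1 rose, miR-1290, and 2 rose adjusted over the list alone (camera adjusted p = 0.041, or adjusted p = 0.170 with an estimated correlation). Its median of 4.54 turned to -0.07 without the miRNAs ever at the lowest count, and the list lost its call there, under all 4 other scalings, and without MCF10A cells 1, MCF10A cells 2 or either MCF7 EV sample. Neither the basal markers (0 of 7, adjusted over the list alone 0, median -0.30) nor the miR-200 family (1 of 5, miR-200c, adjusted over the list alone 1, median -0.17) nor the luminal markers (2 of 11, miR-200c and miR-96, adjusted over the list alone 2, median -0.45) passed as lists, and these 3 medians were above 0 under other scalings. With the run as a block 14 miRNAs passed (2 higher, 12 lower), 11 of the 12 among them. The first run held 1 MCF10A cell sample and 1 EV sample, so its 16 calls (2 higher, 14 lower) and its medians take all spread from the MCF7 pairs and lend no support of their own. The EV sample was assumed to vary like the other groups, the count was 7 without MCF10A cells 3, where the calls of miR-15b, let-7g, miR-16 and miR-29a ended, and scaling to the same total gave 1 higher and 2 lower (miR-1290, let-7f and let-7a), with a shift of the median over all miRNAs of 0.34. Let-7g, miR-16 and miR-29a, whose differences nearest 0 over all alternatives were -0.92, -0.95 and -1.15, kept their calls under none of the 4 other scalings, and miR-15b kept its call under median ratio scaling alone. The calls of miR-15b, let-7g, miR-16 and miR-29a also ended without MCF7 cells 1, those of miR-15b, miR-16 and miR-29a without MCF10A cells 2, that of miR-15b without MCF7 cells 4 and that of miR-29a without MCF7 cells 3.

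The change from cells to EVs was then compared between the lines, which share no sample here. Across the 141 miRNAs the MCF10A and MCF7 changes had r = 0.80 (Spearman rho = 0.75), and over the 118 never at the lowest count r was 0.62, or 0.67 within the first run. Of the 11 miRNAs lower in MCF10A EVs, 10 were among the 27 lower in MCF7 EVs, where independent lists would share 2.11. They were let-7a, let-7d, let-7f, let-7g, miR-15b, miR-16, miR-103, miR-200c, miR-374b and miR-96. MiR-1290 was the 1 that rose in both, where independent lists would share 0.0780. Here too both comparisons used the same estimated spread for each miRNA, so these expected numbers are too low.

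Whether the lines differed in this change was tested as the difference of the differences. By limma 0 miRNAs passed the threshold and 16 had an unadjusted p under 0.05, where 7.05 would by chance, and by limma-voom 0 passed. The largest values were those of the tRNA fragments miR-1274b (4.20, SE 1.38, adjusted p = 0.299), miR-1274a (4.12, SE 1.26, adjusted p = 0.299) and miR-720 (4.10, SE 1.57, adjusted p = 0.400), followed by miR-1260 (3.65, SE 0.92, adjusted p = 0.299) and miR-137 (3.55, SE 2.31). On the other side were miR-26b (-3.15, SE 2.26), miR-1246 (-2.79, SE 4.70), miR-301a (-2.24, SE 0.92), miR-454 (-2.24, SE 2.32) and miR-30e (-2.18, SE 1.18), of which miR-26b, miR-1246 and miR-454, like miR-137, were at the lowest count in some samples. MiR-200b had -2.05 (SE 0.55) and let-7a 1.50 (SE 0.48), both with an adjusted p = 0.299. Within the first run 1 miRNA passed, miR-26b, but it was at the lowest count in both MCF7 EV samples and in MCF10A cells 1 and the MCF10A EV sample, so it shows no difference between the lines.

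**Figure D4:**
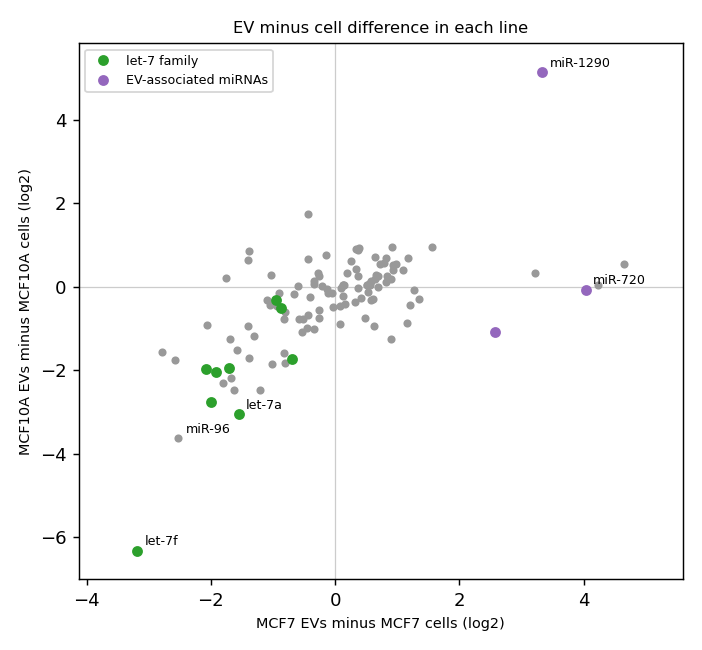
EV minus cell difference in MCF7 (horizontal, log2) and in MCF10A (vertical, log2) for the 118 miRNAs never at the lowest count. Each point is 1 miRNA, with let-7 members in green and EV-associated miRNAs in purple; let-7f lies at -3.18 and -6.32, miR-1290 at 3.33 and 5.14, and miR-720 at 4.03 and -0.07.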

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

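No test in this part was chosen only after the result was seen.

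In the 4 samples of MCF7 cells, 62 quantities were examined for a single sample far from the others (the levels of the named miRNAs, the number at the lowest count, the count total and the share of the 10 highest), by the gap to the nearest sample as a share of the whole range. MiR-200c stood out with 0.847, since MCF7 cells 3 had 11.87 and the others 10.98 to 11.12. MiR-20a+miR-20b had 0.838, with MCF7 cells 3 at 7.13 and the others at 9.22 to 9.63. MiR-301a had 0.858, with MCF7 cells 3 at 7.38 and the others at 8.70 to 8.92. MiR-429 had 0.846, with MCF7 cells 4 at 8.27 and the others at 6.89 to 7.10. Chance marks about 1 in 20 such groups, or 3.1 of 62, so these 4 are about as many as chance would mark. All of them except miR-429 fell on MCF7 cells 3, which a comparison of numbers does not weigh. Over the 118 miRNAs never at the lowest count, MCF7 cells 3 had r of 0.892, 0.875 and 0.905 with MCF7 cells 1, 2 and 4. The lowest r between the other MCF7 cell samples was 0.956, for MCF7 cells 1 and 4. MCF7 cells 3 thus stood apart from the other MCF7 cells. No technical or biological explanation was tested for this or for the 4 flagged values.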

How the results depend on the processing

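The run as a block, each run alone, the filters on the lowest count and on a log2 value of 8, the values without a pseudocount and limma-voom were chosen only after the data were seen. Except where shown by fewer samples or fewer miRNAs, the cause was not tested.

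No named miRNA past the threshold reversed under any alternative run. Of the 176 named pairs of an miRNA and a comparison, 25 had both signs over the scalings, 0 of them past the threshold. For single miRNAs, 4335 values kept their side of the threshold, 288 lost the call and 80 gained it. For lists these were 1685, 32 and 22. The kept values include 176 for single miRNAs and 70 for lists from each filter setting that removed 0 miRNAs. Those settings could not change a value. Values past the threshold in neither fit also count as kept, so the kept numbers do not measure how well the calls held.

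MCF7 EVs against MCF10A EVs gave 4 miRNAs. There were 9 scaled to the geometric mean of the 100 highest, 2 with quantile normalization, 7 with limma-trend, 0 by limma with only the groups compared (31 at an unadjusted p under 0.05), 14 without any miRNA ever at the lowest count, 7 with a log2 value of at least 8 in 2 samples, 10 with the run as a block, 14 within the first run and 8 by limma-voom. MCF7 cells against MCF10A cells gave 44, and 28 with only the groups compared, 27 with a log2 value of at least 8, 26 within the first run and 22 within the second. MCF7 EVs against MCF7 cells gave 38, and 25 with quantile normalization and 25 with only the groups compared. MCF10A EVs against MCF10A cells gave 12, and 3 scaled to the same total, and by limma 0 with quantile normalization (28 at an unadjusted p under 0.05) and 0 with only the groups compared (20). The difference of the differences gave 0, and 1 within the first run. Of the list tests 11 passed, 6 scaled to the same total, 5 with a log2 value of at least 8, and 0 by camera with an estimated correlation.

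With the replicate number as a block, for which nothing shows that the numbers pair samples, these comparisons gave 1, 18, 1 and 0 (23 at an unadjusted p under 0.05) by limma, and 13 lists passed.

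Leaving out 1 sample at a time gave 0 to 11 for MCF7 EVs against MCF10A EVs, 18 to 53 for MCF7 cells against MCF10A cells, 0 to 52 for MCF7 EVs against MCF7 cells, 7 to 16 for MCF10A EVs against MCF10A cells and 8 to 14 for the lists. The highest count of each of these comparisons with MCF7 samples came without MCF7 cells 3. With MCF7 EVs 1 or 2 left out, the lone EV sample was assumed to vary like the other groups. The share of the 20 most abundant was 84.8% to 91.3%.

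The geometric mean, median ratio and quantile scalings shifted the median over all miRNAs by between -0.32 and 0.52 in the 4 comparisons. The filters on samples above background and on 5 times the lowest value removed 0 miRNAs, so they tested nothing. DESeq2 was not run, since the values are log2. The fitted differences of the 23 miRNAs ever at the lowest count depend on the pseudocount.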

Other observations

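The tests of depth, of the cell line and of a correction behind the lowest counts, the test of the RNA state of single samples, and the number of calls never at the lowest count in the other splits, were chosen only after the result was seen.

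Other lists differed between MCF7 and MCF10A cells in single members. MiR-34c-5p fell by 1.04, as 1 of 3 members of the p53-regulated miR-34 family, with 1 adjusted over the list alone. MiR-148a fell by 1.67 as 1 of 2 members of the miR-148 family, and miR-29a fell by 1.39 as 1 of 3 members of the miR-29 family, with 1 adjusted over the list alone in each. MiR-30d rose by 1.24 (1 of 5 members), miR-99a by 1.69 (1 of 7 in the miR-99/100 and miR-125 clusters) and miR-16 by 0.88 (1 of 3), with 1, 1 and 2 adjusted over the list alone. Let-7b fell by 1.12 as 1 of 9 members, and 0 passed adjusted over the list alone. Neither member of the miR-181 family passed, nor did miR-10a, nor any of the 5 EV-associated miRNAs. In the miR-23/27/24 clusters miR-23b was the 1 that rose, and 1 adjusted over the list alone. In MCF7 EVs against MCF7 cells, miR-106b (-1.69) and miR-19b (-1.57) fell among the 9 of the miR-17-92 and paralogous clusters, miR-148b fell as 1 of 2 of its family, and both listed members of the miR-183 cluster, miR-183 and miR-96, fell. In MCF10A EVs against MCF10A cells 1 of 2 of the miR-183 cluster fell, miR-96, and 1 of 3 of the miR-29 family, miR-29a.

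Few names on the lists of markers of other cells and of serum were among the 141. Of the names on the haematopoietic, liver and serum, and pluripotent and placental lists, 0 were among the 141. This says nothing of their levels, since 141 of 654 assayed miRNAs were listed. Other miRNAs of these cells, which the lists do not name, may be among the 141. MiR-126, of stromal and endothelial cells, was higher by 1.17 in MCF7 than in MCF10A cells (adjusted p = 0.00951). The muscle marker miR-208a passed in no comparison, nor did miR-379, miR-539 and miR-655, the names found from the 14q32 list. These were at the lowest count in most samples of the first run. Other miRNAs of the 14q32 cluster, which the list did not find, are not covered by this. Of the 2 listed neural markers, miR-128 and miR-137, neither passed, and miR-137 was at the lowest count in the MCF10A EV sample.

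The difference between MCF7 and MCF10A cells was set against other groupings of the same 7 cell samples. Of the 35 splits into 4 and 3, only 1, the real one, gave as many as 44 miRNAs past the threshold. With only 35 splits, which were not kept within runs, this cannot exclude chance. Every other split also mixed the lines within a group, which widens the spread. The highest of the others gave 16, and it was the split by run. Since the runs were defined from the lowest counts, that split finds those miRNAs by construction, and 1 of the 16 was never at the lowest count, against all 44 of the real split. In the real split both groups held samples of both runs, which widens the spread of miRNAs at the lowest count in 1 run. Such miRNAs could hardly pass there, so this contrast lends the 44 no support.

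In MCF10A cells 1, 19 miRNAs were at the lowest count. At their level in MCF10A cells 2 and 3 a median of 75.8 counts would be found there, with a lowest value of 17.4, which argues against lower depth. Of the 19, 1 was also at the lowest count in MCF10A cells 2 or 3, which argues against a property of MCF10A cells, while 18 were there in MCF7 EVs 1, another line and another kind of sample. In the rest of the first run fewer were shared, with 17 in the MCF10A EV sample and 12 in MCF7 EVs 2. MCF7 cells 1 shared 14 and MCF7 cells 2 shared 9, and there miR-26a had 4556 and 7929 counts. A correction that set the same miRNAs to the lowest count throughout the run would therefore not account for all these values. A background or probe correction that differed between samples of the run may have set them, which stays a hypothesis. The biological difference between the cultures of the runs was not tested and stays open.

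MiR-720, miR-1274a and miR-1274b were higher in MCF7 EVs than in MCF7 cells by a mean of 4.31. With every sample at the same total the mean was 3.39 (SE 0.72), and the 3 passed with adjusted p of 0.0152, 0.00321 and 0.00582, which argues against scaling by a few very high miRNAs as the whole cause. The RNA state of single samples stays open, since the mean of the 3 ranged over 3.28 between MCF10A cell samples and over 1.33 between MCF7 cell samples. The 3 held 6.90% of the signal in MCF10A cells 2 and 38.9% in MCF10A cells 3, against 64.9% and 54.7% in the MCF7 EV samples. Release of tRNA fragments by MCF7 cells may add to the difference, and it was not tested.

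Of the 9 let-7 members 6 fell in MCF7 EVs and 4 in the MCF10A EV sample against the cells. The EV minus cell difference fell with the cell level, with slopes of -0.19 in MCF7 and -0.33 in MCF10A. Since the cell level is subtracted in that difference, such slopes can arise without any compression. Beside that trend the let-7 medians were -1.37 and -0.94. They lay at the percentiles 0.02 and 0.03 of 10000 random lists, or 0.10 and 0.22 of lists matched for level. Let-7 was thus lower than miRNAs of like level, which argues against compression of abundant miRNAs as the whole cause. Under the 4 other scalings the let-7 median lay between -2.62 and -1.44, which argues against the scaling between cells and EVs. The random lists treat the near-identical let-7 probes as independent, and with an estimated correlation the lists had an adjusted p = 0.159 in MCF7 and 0.170 in MCF10A. Retention of let-7 in cells may be a cause, as may losses during EV isolation or RNA extraction, and neither was tested.

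The hypothesis that the difference between the cell lines is carried into their EVs was tested with the cell samples of the second run. These shared no sample with the EVs, and no run by the grouping drawn from the lowest counts. The labels name no run, and the grouping was added after the data were examined. Over the 118 miRNAs never at the lowest count the slope of the EV difference on the cell difference was 0.589 (SE 0.07, r = 0.62). This is consistent with EVs that carry much of the line's miRNA profile, which may include RNA from broken cells, and the test does not separate the routes. The SE treats miRNAs as independent, which family members are not.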
